A study of Homo sapiens with 4 samples.

How the data were processed

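RNA from 4 cultures was measured by sequencing. KMS18 and KMS28BM are human multiple myeloma cell lines that carry the t(4;14) translocation, which places NSD2 and FGFR3 under immunoglobulin heavy chain control. Each line gave 1 library with a luciferase control construct and 1 library with a stable knockdown of PKCα, the protein kinase encoded by PRKCA. Per the labels' protocols, total RNA was extracted with a column kit and 100 ng of it went into a TruSeq RNA version 2 library, a kit that does not keep strand.

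The authors deposited 1 gene table per library with an estimated (expected) count, an FPKM value, a gene length, a symbol and functional terms for each gene, per the file headers. The authors' expected counts need not be whole, and 52.2% to 54.0% of them lay within 0.005 of a whole number. The deposited FPKM values are fragments scaled to the listed gene length and to library size, and the smallest listed value was 0.01. The submitters' processing notes name STAR, Bowtie2, HISAT and the builds GRCh37 and hg19, without saying which step used which. The counting program is not given in the sources used here. The tables carry no coordinates. The chromosome positions given below come from the GENCODE annotation, version 29, on the GRCh38 build, matched by gene identifier, and were not converted to another build.

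The tables listed 23844 gene identifiers, of which 842 were transcripts without a known gene and 3259 had no symbol. In 820 cases several identifiers shared a symbol (2477 identifiers), among them the HLA genes, which the annotation holds in alternate copies. Expected counts and FPKM were summed over identifiers that share a symbol, which gave 22187 genes. Genes with near-identical copies (the HLA genes, IGHA1 and IGHA2, EIF3CL, GAGE12E, histone genes, and GAPDH and ribosomal protein genes with their pseudogenes) are uncertain, because the counting could split their reads. The same holds for genes that overlap others, such as FAM120AOS, SNURF, DNAJC25-GNG10 and TMED7-TICAM2, since strand was not kept.

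The libraries held 37940949, 37957404, 39507281 and 39100504 expected counts, in the order KMS18 control, KMS18 knockdown, KMS28BM control and KMS28BM knockdown. Intervals on counts (exact Poisson, 95%) cover counting error only, and they are wide for genes with few counts. Each line has 1 library per construct, so a difference within a line has no replicate check and no p-value. The 2 lines are the only replication of the knockdown. A p-value over both lines therefore measures how alike the lines moved, not the spread between cultures of a line.

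The test over both lines was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on expected counts rounded to whole numbers. It used TMM scaling and edgeR's default filter on low counts (minimum count 10), with cell line and construct in the model. The cell line is a block because the labels give each line 1 control and 1 knockdown library, so the libraries are paired by their line. This left 1 residual degree of freedom, moderated over 14870 genes to a prior of 5.85, and Benjamini-Hochberg adjustment at 0.05. The same fit gave the difference between lines. Sizes within a line are differences of log2(FPKM + 1), a scale that understates the change of low genes. A gene passed the size rule at an absolute log2 fold of 1 and at least 1 FPKM in 1 of the 2 libraries.

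Of 32 gene lists, the 31 with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01) on the same design. Estimated correlation and fry were the alternatives. With an estimated correlation camera takes its p-value from the 1 residual degree of freedom, so that setting had little power to call any list. Its adjusted p-values, many of them tied at 0.69, do not tell the lists apart. The correlations it estimated, themselves rough with 1 residual degree of freedom, were 1 for the S phase, G2/M and ATF4 lists and 0.758 for ribosomal proteins. They were 0.022 for the unfolded protein response and -0.053 for plasma cell identity. Where the true correlation is above the preset, the preset gives too small a p-value. Within a line, a list's median was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. The 6 cell type marker lists were read as levels. The lists, the tests, the alternatives listed first and the rule for naming genes were fixed before the data were examined. That rule takes the PKC family, NSD2 and FGFR3; 12 genes in each direction with the largest smaller fold over the 2 lines, at 5 FPKM or more; 6 in each direction per line; 3 in each opposite pattern; up to 4 per list; and 5 in each direction between lines. Rows without a symbol, sex-linked marker genes, immunoglobulin variable segments and small RNA genes stayed outside the ranked parts of the rule. It named 174 genes, of which those that carry a comparison are given here. Some members of the lists are counted and tested with their list but not reported here by name.

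On simulated counts made from these libraries with 200 changed genes, the fit recovered 31.5%, 68% and 75.5% of genes changed by a log2 fold of 0.5, 1 and 1.5. It made 4, 6 and 4 false calls. A simulated list of 25 genes lowered by 0.4 was called, and 0 of 20 unchanged lists were. The simulated genes were drawn independently, so this does not cover false calls of lists whose genes vary together. Alternatives covered the pseudocount, the scaling, the floor, the filter, the block, limma on log2(FPKM + 1), DESeq2 1.42.0 and leaving out each library. Others were added after the data were seen. These were edgeR's robust and bias-adjusted fits, identifiers kept separate, leaving out immunoglobulin and mitochondrial genes, a correction for GC content and transcript length, the same genes without it, and leaving out genes that hold a short sequence found in the 3' UTR search. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.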

Results

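The data are 4 RNA sequencing libraries from the myeloma lines KMS18 and KMS28BM, with 1 luciferase control and 1 PKCα knockdown library per line. Both lines carry t(4;14). The libraries held between 37940949 and 39507281 expected counts, and between 11100 and 11591 genes reached 1 FPKM in each. Immunoglobulin genes took 4.66% and 4.28% of the counts in KMS18 (control, then knockdown) and 1.22% and 0.79% in KMS28BM. Mitochondrial transcripts took 7.12%, 7.52%, 8.39% and 8.29% in the same order, and ribosomal protein genes took 6.84%, 8.44%, 6.87% and 7.50%. The design asks what lower PKCα does to the transcriptome of t(4;14) myeloma cells, and whether it does so alike in both lines.

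PRKCA, the knockdown target (ENSG00000154229, chromosome 17, 66302636 to 66810743, plus strand, GRCh38), was lower in both knockdown libraries. It went from 7.46 to 1.47 FPKM in KMS18 and from 10.86 to 2.43 FPKM in KMS28BM, which left 19.7% and 22.4% of the control level. The expected counts were 2031 and 395 in KMS18, and 3414 and 741 in KMS28BM. On log2(FPKM + 1) the difference was -1.78 and -1.79. The log2 ratio of the counts had 95% Poisson intervals of -2.58 to -2.27 and -2.39 to -2.15. Over both lines PRKCA fell by 2.34 on the log2 scale (SE 0.11, adjusted p = 0.00153, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 lines), and it was lower in 2 of 2 lines.

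PRKCA was the one PKC family member of 10 measured that passed the test (1 rose and 2 fell when adjusted over the list alone). PRKCB was at 0.56 and 1.41 FPKM in KMS18 and at 0.84 and 1.27 FPKM in KMS28BM (log2 difference 0.88, SE 0.22, edgeR adjusted p = 0.0536). PRKCI had a log2 difference of -0.41 (SE 0.10, edgeR adjusted p = 0.0572). PRKCD, PRKCE, PRKCQ, PRKCZ, PRKD2 and PRKD3 had edgeR adjusted p-values from 0.164 to 0.787. The list was called lower by camera (adjusted p = 0.0152), and its adjusted p was 0.69 with an estimated correlation, 0.137 without the cell line block, 0.167 with no filter and 0.3 with limma on log2(FPKM + 1). PRKCA itself is a member.

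The translocation genes did not pass the test. NSD2, a histone methyltransferase (chromosome 4, 1871424 to 1982207, plus strand, GRCh38), was at 246 and 184 FPKM in KMS18 and 172 and 112 FPKM in KMS28BM (log2 difference -0.44, SE 0.11, edgeR adjusted p = 0.0579). FGFR3, a receptor tyrosine kinase (chromosome 4, 1793293 to 1808872, plus strand, GRCh38), was at 437 and 261 FPKM in KMS18 and 593 and 527 FPKM in KMS28BM (log2 difference -0.48, SE 0.16, edgeR adjusted p = 0.105). Both were lower in 2 of 2 lines, and 2 of 2 passed when adjusted over the list alone.

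**Figure D1:**
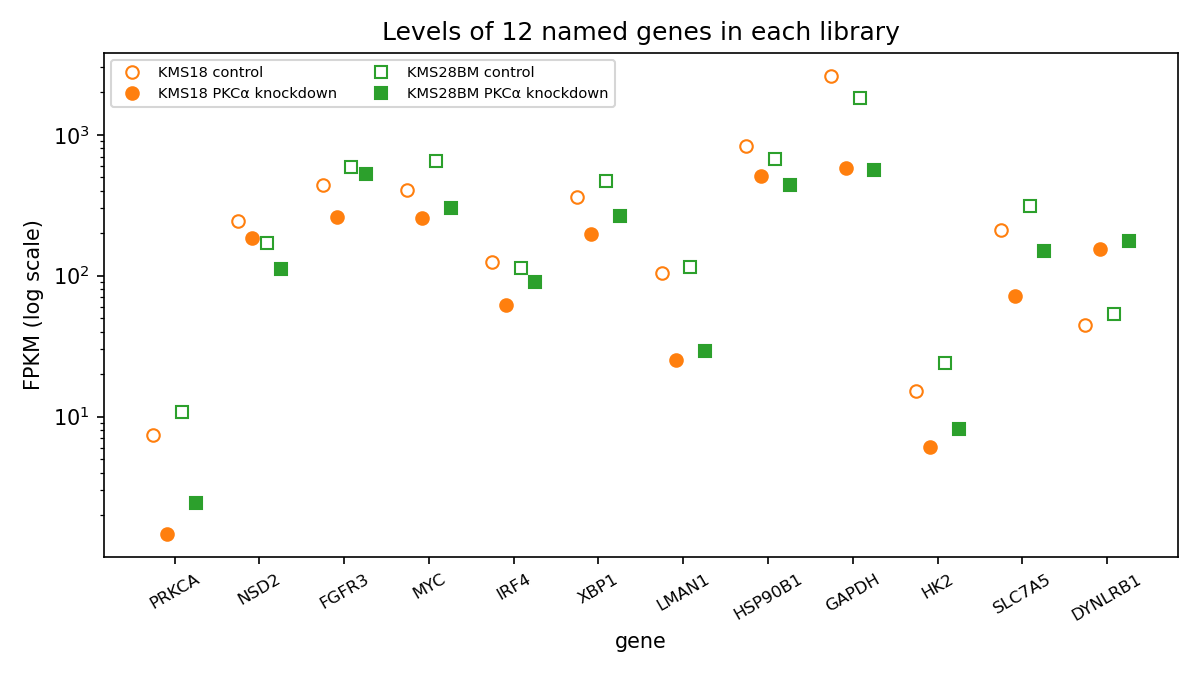
FPKM on a log axis for 12 genes, with open symbols for control and filled symbols for knockdown libraries, circles for KMS18 and squares for KMS28BM, 1 library per symbol. PRKCA lies at 7.46 and 10.86 FPKM in the controls and at 1.47 and 2.43 FPKM in the knockdowns, and DYNLRB1 moves the other way.

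Several of the genes lowest in both lines act in the secretory pathway. LMAN1, a cargo receptor between the endoplasmic reticulum (ER) and the Golgi, went from 105 to 25.1 FPKM in KMS18 and from 114 to 29.2 FPKM in KMS28BM. Its log2 difference over both lines was -2.04 (SE 0.10, edgeR adjusted p = 0.00153). SSR1, a subunit of the translocon-associated complex, had -1.72 (SE 0.10), ATP2A2, the ER calcium pump, had -1.72 (SE 0.10), RCN1, an ER calcium-binding protein, had -1.73 (SE 0.10) and SEC24A, a coat protein of ER exit vesicles, had -1.57 (SE 0.10). GAPDH, a glycolytic enzyme often used as a reference gene, went from 2614 to 582 FPKM in KMS18 and from 1823 to 561.5 FPKM in KMS28BM. UCHL1, a ubiquitin hydrolase, RPA3, DESI2, FAM120AOS and BHLHA15, a transcription factor of secretory cells, completed the 12 genes lowest in both lines, with edgeR adjusted p from 0.00292 to 0.0056. Of these 12, which include PRKCA, 10 carry AGTCTAA, CAGTCTA or both joined in their 3' UTR, sequences found by a search made after the calls, and GAPDH and BHLHA15 do not.

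The genes highest in both lines were led by DYNLRB1, a dynein light chain, and NECTIN1, a cell adhesion protein. DYNLRB1 went from 44.3 to 154 FPKM in KMS18 and from 53.1 to 176 FPKM in KMS28BM, a log2 difference of 1.69 (SE 0.10, edgeR adjusted p = 0.00164). NECTIN1 rose by 1.82 on the log2 scale (SE 0.10), SNX15, a sorting nexin, by 1.44 (SE 0.11), NR1H2, the liver X receptor beta, by 1.42 (SE 0.11), and ARNTL, a core clock factor, by 1.46 (SE 0.15). FAM234A, HIST1H2AG, VAMP3, CPTP, GEM, TBC1D17 and MYO1D were the other 7 of the 12, with edgeR adjusted p from 0.0034 to 0.00968.

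Over both lines, 1312 of 14870 genes passed the edgeR quasi-likelihood test (3919 at an unadjusted p under 0.05). Of these, 531 rose and 781 fell, so 59.5% of the calls were lower. In the same fit with median of ratios scaling 56.9% were lower. The share was 53.6% at 5 CPM in at least 2 libraries, 62.4% with DESeq2 and 66.2% with no filter on low counts. Limma on log2(FPKM + 1), another test, measure and gene set (11967 genes), gave 502 higher and 450 lower calls, 47.3% lower. Without the cell line block the edgeR test made 0 calls (215 genes at an unadjusted p under 0.05).

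Within each line, sizes alone were compared. In KMS18, 96 genes were higher and 76 lower past the size rule among 11742 genes. In KMS28BM, 142 were higher and 86 lower among 11455. Among the 10599 genes at or above the floor in both, 24 were higher in both and 36 lower in both, where independent lists would share 0.8 and 0.5. Past the rule in opposite directions were 2 genes, where 1.2 would be. The folds of the lines had a Pearson correlation of 0.65 and a Spearman correlation of 0.62 across genes, which are not independent replicates.

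**Figure D2:**
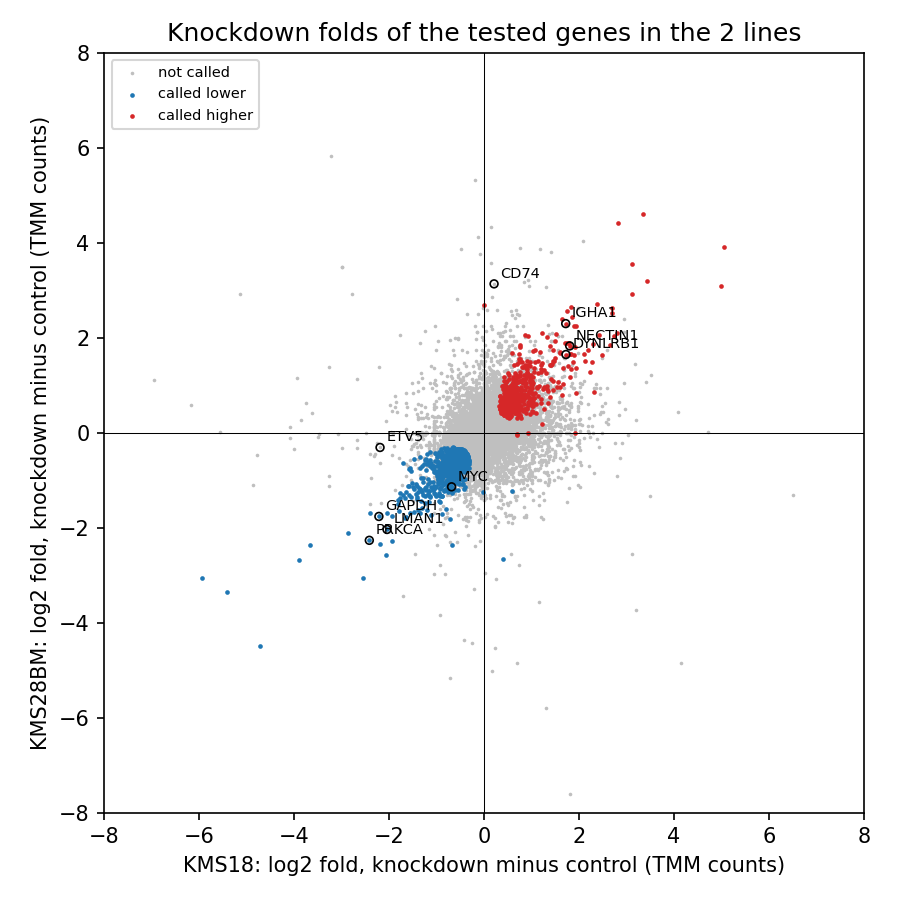
Log2 fold of knockdown against control for the 14870 tested genes, KMS18 on the x axis and KMS28BM on the y axis, each point a gene from 1 library pair per line. The 781 genes called lower (blue) and 531 called higher (red) lie mostly at the lower left and the upper right, and CD74 lies at 0.21 in KMS18 and 3.14 in KMS28BM.

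In KMS18 the highest folds, apart from the 12 genes named in each direction over both lines, belonged to HIST2H2BE (1.47 to 7.76 FPKM), HIST1H2AC (4.83 to 19.5 FPKM), RAB37 (11.3 to 41.9 FPKM), HIST1H2BK, HSD17B10 and HELZ2. The lowest belonged to ETV5, a transcription factor downstream of FGF receptor signalling (14.1 to 2.79 FPKM in KMS18, 10.9 to 9.06 FPKM in KMS28BM), ANXA2 (122 to 37.3 FPKM), EIF4G2, PGAM1, GAGE12E and AC126755.2. Of these, ANXA2, EIF4G2 and PGAM1 also passed the size rule lower in KMS28BM. GAGE12E was listed at 5.45 FPKM in the KMS18 control alone, and it belongs to a family of near-identical genes.

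In KMS28BM the highest folds, with the same genes set apart, belonged to EIF3CL (2.17 to 27.4 FPKM), a near-identical copy of EIF3C, and CD74, the class II invariant chain (5.63 to 51.8 FPKM). IGHA1, SLC6A9, ITGB7, a homing integrin subunit (10.1 to 38.2 FPKM), and LILRB4, an inhibitory receptor (11.1 to 41.7 FPKM), followed. ITGB7 rose over both lines (log2 difference 1.27, SE 0.23, edgeR adjusted p = 0.0221), as did LILRB4 (2.11, SE 0.20, adjusted p = 0.00482), while CD74 had an adjusted p of 0.168. The lowest folds in KMS28BM were those of HID1, TMED7-TICAM2, SGK3, PRRC1, PUDP and HK2. LILRB4, PRRC1, PUDP and HK2 passed the size rule in the same direction in KMS18. Across the lines, the genes furthest apart in sign were SNURF, ABLIM1 and ZBP1, higher in KMS18, and CCL3, DNAJC25-GNG10 and FRMD6, higher in KMS28BM, and the difference between lines has no test. SNURF rested on 46 and 60 counts in KMS18, where the 95% Poisson interval of its log2 ratio was -0.25 to 0.91.

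The unfolded protein response list fell: 16 of its 24 measured members fell and 0 rose (21 fell adjusted over the list alone). PDIA4, a disulfide isomerase, fell by 0.85 on the log2 scale (SE 0.10, edgeR adjusted p = 0.00891), HSP90B1, the ER HSP90, fell by 0.72 (SE 0.11), and MANF fell by 0.71 (SE 0.10). HSPA5, the main ER chaperone, named after its value was seen, fell by 0.69 (SE 0.11, edgeR adjusted p = 0.0144). Camera gave an adjusted p of 6.72e-14, and the adjusted p with an estimated correlation was 0.69. Its median lay at percentile 0.0 of random lists in both lines.

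The plasma cell identity list fell as well, with 10 of 19 members lower and 1 higher (11 and 1 adjusted over the list alone). XBP1, the transcription factor of antibody-secreting cells, fell by 0.90 (SE 0.10, edgeR adjusted p = 0.00671), from 360 to 196 FPKM in KMS18 and 472 to 265 FPKM in KMS28BM. SLAMF7, a surface antigen, fell by 0.95 (SE 0.14), SEC11C by 0.90 (SE 0.10) and MZB1 by 0.83 (SE 0.10). CD38 rose (0.59, SE 0.10, edgeR adjusted p = 0.0193) and was named after its value was seen. Camera gave an adjusted p of 1.76e-09, against an adjusted p of 0.69 with an estimated correlation.

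Among 22 myeloma driver and IMiD-response genes, 4 fell and 1 rose, the same numbers as adjusted over the list alone. MYC fell by 0.91 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0128), from 405 to 258 FPKM in KMS18 and 646 to 304 FPKM in KMS28BM. NRAS fell from 47.8 to 17.9 FPKM in KMS18 and from 28.2 to 13.2 FPKM in KMS28BM (edgeR adjusted p = 0.00345), IRF4 fell by 0.73 (SE 0.15) and IKZF3, a target of lenalidomide-bound cereblon, by 0.56 (SE 0.10). NRAS and IKZF3 carry the 3' UTR sequence CAGTCTAA. Camera called the list lower (adjusted p = 0.0128, and adjusted p = 0.69 with an estimated correlation), and this call was lost without genes that hold AGTCTA (adjusted p = 0.178), with limma on log2(FPKM + 1) (0.0761), at 5 CPM (0.0513) and with no filter (0.0592).

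Of 29 MYC targets and ribosome biogenesis genes, 7 fell and 0 rose (18 fell adjusted over the list alone), among them GNL3 (-0.70, SE 0.09), NOP56 (-0.62, SE 0.09), NCL (-0.56, SE 0.11) and ODC1 (-0.51, SE 0.10). The camera adjusted p was 1.01e-07, and 0.69 was the adjusted p with an estimated correlation. Ribosomal protein genes went the other way as a list (camera adjusted p = 0.00209, adjusted p = 0.767 with an estimated correlation). The median log2 difference of its 63 members was 0.16, with 0.267 in KMS18 and 0.052 in KMS28BM on TMM counts. One of them, RPL5, fell (-0.56, SE 0.10, edgeR adjusted p = 0.0221), and 0 passed when adjusted over the list alone.

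Glycolysis genes fell in part: 4 of 22 fell and 0 rose (5 fell adjusted over the list alone). These were GAPDH (-1.99, SE 0.14, edgeR adjusted p = 0.00292), HK2 (-1.51, SE 0.11), PGAM1 (198 to 84.2 FPKM in KMS28BM) and PDK1, a brake on pyruvate oxidation (-0.65, SE 0.11). HK2 and PGAM1 carry CAGTCTA in their 3' UTR, and PDK1 the shorter AGTCTA. Of the 12 members without AGTCTA in any transcript, GAPDH alone fell. The list was called lower by camera (adjusted p = 2.04e-05, adjusted p = 0.69 with an estimated correlation, and 0.00139 over those 12 members). Its median on log2(FPKM + 1) was -0.21 in KMS18 (percentile 0.83) and -0.05 in KMS28BM (percentile 12.3). Hypoxia and HIF targets overlapped it, with 7 of 17 lower and 0 higher (9 lower adjusted over the list alone), led by HK2, ANKRD37 (-0.85, SE 0.11), ERO1A (-0.83, SE 0.09) and KDM3A (-0.73, SE 0.11). Camera gave that list an adjusted p of 1.36e-06, and its adjusted p with an estimated correlation was 0.69. Of its members HK2 and ERO1A carry AGTCTAA or CAGTCTA in their 3' UTR. Among its 8 members without AGTCTA in any transcript 1 fell (camera adjusted p = 0.0148). Their medians on TMM counts were -0.264 in KMS18 and -0.256 in KMS28BM, against -0.291 and -0.584 over all 17.

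Of 24 TCA cycle genes, IDH2, SDHD and PC rose and CS, citrate synthase, fell (-1.14, SE 0.12, edgeR adjusted p = 0.0056), with 3 and 1 also adjusted over the list alone and a camera adjusted p of 0.189. Of 9 pentose phosphate genes 1 rose and 1, RPE, fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.829). None of 39 nuclear-encoded oxidative phosphorylation genes passed the edgeR test, alone or adjusted over the list alone, and the list was called higher by camera (median 0.15, adjusted p = 0.00973, adjusted p = 0.69 with an estimated correlation and 0.0996 over the 21 members without AGTCTA, whose medians of 0.185 and 0.137 by line compare with 0.185 and 0.124 over all 39). The 12 mitochondrial genome transcripts had 0 calls on either count and a camera adjusted p of 0.705. Of 28 cholesterol and SREBP targets, MVK rose and 3 fell, among them MSMO1 and ACACA (2 and 6 adjusted over the list alone, camera adjusted p = 0.0669).

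SLC7A5, the large neutral amino acid transporter, fell by 1.37 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0056), from 210.2 to 71.9 FPKM in KMS18 and 311 to 150 FPKM in KMS28BM. Its partner SLC3A2 fell by 0.69 (SE 0.11), SLC7A11 by 0.98 (SE 0.16) and SLC38A5 by 0.89 (SE 0.10), while SLC36A1, a lysosomal exporter, rose by 1.08 (SE 0.13). In all, 6 of 16 amino acid transporters fell and 1 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.713 with an estimated correlation, 0.141 without the cell line block and 0.0764 with limma on log2(FPKM + 1)). Of 25 ATF4 targets, 4 fell and 0 rose (the same adjusted over the list alone), namely SLC7A5, SLC3A2, SLC7A11 and MTHFD2 (camera adjusted p = 0.00434, adjusted p = 0.765 with an estimated correlation and 0.0559 with limma on log2(FPKM + 0.1)). None of 20 aminoacyl-tRNA synthetases passed on either count (camera adjusted p = 0.105). Of 29 mTORC1 pathway components, LAMTOR1 and EIF4EBP2 rose and TSC1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0926).

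Of 27 S phase genes 5 fell and 0 rose (12 fell adjusted over the list alone), among them CDC6 (-0.92, SE 0.12), CCNE2 (-0.92, SE 0.20) and FEN1 (-0.66, SE 0.11). Camera gave an adjusted p of 4.28e-05, and 0.724 was the adjusted p with an estimated correlation. Of 25 G2/M genes, HMMR and CDK1 fell (4 adjusted over the list alone), with a camera adjusted p of 0.00209 and an adjusted p of 0.765 with an estimated correlation. By line, on log2(FPKM + 1), the S phase median was -0.419 in KMS18 (percentile 0.0) and 0.026 in KMS28BM (percentile 39.4), and the G2/M median was -0.271 (percentile 0.02) and -0.005 (percentile 21.6). Replication-dependent histone genes rose, 6 of 13 and 0 lower (9 adjusted over the list alone), led by HIST1H2AG (1.66, SE 0.21) and HIST2H2BE (1.57, SE 0.34), with a camera adjusted p of 4.76e-06 and an adjusted p of 0.69 with an estimated correlation. These genes share near-identical copies, and most of their mRNA carries no poly(A) tail.

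The interferon response list rose, with 5 of 26 higher and 1 lower (11 and 1 adjusted over the list alone). IFIT3 (2.10, SE 0.34), IFIT5 (1.89, SE 0.28) and ISG15 (0.82, SE 0.17) rose, as did GBP1 and IRF1, and ISG20 fell, the last 3 named after their values were seen. IFIT3 was at 1.36 and 5.47 FPKM in KMS18 and 0.02 and 0.19 FPKM in KMS28BM. Camera gave an adjusted p of 0.00125, and the adjusted p was 0.69 with an estimated correlation and 0.139 without genes that hold AGTCTA, where 15 members had medians of 0.306 in KMS18 and 0.391 in KMS28BM against 0.332 and 0.443 over all 26. In the B cell programme list CIITA, the class II transactivator, rose and BACH2 fell (3 and 1 of 15 adjusted over the list alone, camera adjusted p = 0.123), both named after their values were seen. IGHA1 and IGHA2 were the 2 of 10 immunoglobulin constant genes that rose, with 0 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.587).

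Of 30 proteasome genes, PSMD14, PSMD2, PSMA1 and PSMD12 fell and 0 rose (4 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.713 with an estimated correlation and 0.0513 at 5 CPM). Of 16 NF-kB targets, TRAF1 rose while ICAM1 and NFKBIA fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.829). Among 22 BCL2 family and apoptosis genes, BCL2L11, which encodes BIM, rose and 3 fell, among them PMAIP1 and MCL1 (1 and 4 adjusted over the list alone, camera adjusted p = 0.705). Of 21 p53 targets, TNFRSF10B rose while TP53INP1 and AEN fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.372). JUNB was the 1 of 21 MAPK feedback genes that fell, with 0 higher (the same adjusted over the list alone, camera adjusted p = 0.478). ITGB7 was the 1 of 17 adhesion genes that rose (the same adjusted over the list alone, camera adjusted p = 0.105), and NSD3 was the 1 of 24 chromatin genes that fell (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.091). Of 14 housekeeping genes, GAPDH, HPRT1 and PPIA fell (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.206). Members named here outside the naming rule (MCL1, AEN, TSC1, ACACA) were named after their values were seen. Of the lower list members named above and not yet marked for it, RPE, MSMO1, SLC7A11, TSC1, CCNE2, HMMR, PSMD14, PSMA1, MCL1, NSD3 and PPIA also carry AGTCTAA or CAGTCTA in their 3' UTR. Counting members not named, 3 of the 16 lower unfolded protein response genes carry such a site, as do 2 of the 5 lower S phase genes, CCNE2 included. Among members without AGTCTA in any transcript, 0 fell in the chromatin, mTORC1, pentose phosphate and G2/M lists, and 1 proteasome gene fell. The count of 0 decides nothing, because the only lower members of those lists were NSD3, TSC1, RPE, HMMR and CDK1. All but CDK1 are carriers named above, and CDK1 holds AGTCTA in a transcript but not in the 3' UTR searched.

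In all, camera called 16 of 31 lists at its preset correlation, 4 higher and 12 lower. It called 0 with an estimated correlation, a setting with little power here. By percentile, MYC targets, hypoxia targets, plasma cell identity and the unfolded protein response lay under 2.5 in both lines. The B cell programme, interferon response, oxidative phosphorylation, histones and ribosomal proteins lay at or above 99.7 in both lines. In KMS28BM the B cell programme's median was 0.87 on log2(FPKM + 1) and 1.08 on TMM counts over the 9 members at 1 FPKM or more in at least 1 library of the line. Over all 15 tested it was 0.00 on TMM counts. HLA-DRA (0.91 to 4.31 FPKM) and HLA-DPA1 (0.73 to 3.29 FPKM) reached that floor in KMS28BM only with the knockdown. The list's percentile there thus rests in part on members chosen where they were high.

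**Figure D3:**
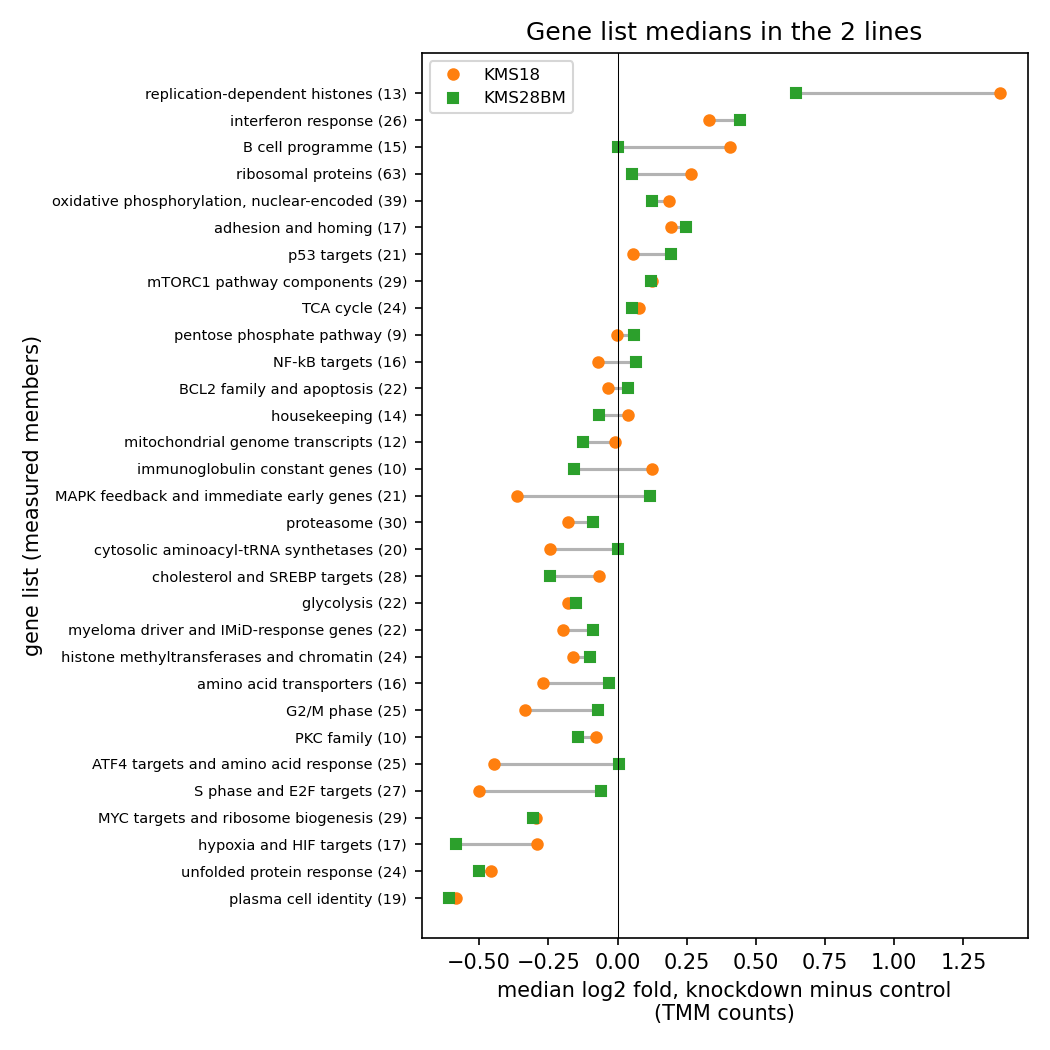
Median log2 fold of knockdown against control (x axis) of each gene list (y axis, measured members in brackets), circles for KMS18 and squares for KMS28BM, 1 library pair per line. The plasma cell identity list lies at -0.58 and -0.61, and the histone list at 1.38 and 0.65.

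The lines differed far more than the constructs. In the same fit 9351 of 14870 genes passed the edgeR test between lines, 4555 higher and 4796 lower in KMS28BM. KIF1A, a neuronal kinesin, was higher in KMS28BM by 11.21 on the log2 scale (SE 0.29, edgeR adjusted p = 5.26e-07), as were DBN1, MARCKSL1, EMP3 and IGLL5. HLA class II genes were lower there: HLA-DRA was at 2390 and 3265 FPKM in KMS18 and at 0.91 and 4.31 FPKM in KMS28BM (control, then knockdown; log2 difference -10.34, SE 0.43, edgeR adjusted p = 3.81e-06). HLA-DRB3, HLA-DPB1, HLA-DPA1 and CD74 were the other 4 of the 5 lowest by log2(FPKM + 1), the scale of the ranking. On the edgeR scale the fitted value of PRKCZ was lower still, at -12.62 (edgeR adjusted p = 6.58e-06). The size of so extreme a value is uncertain, since it rests on very few counts, if any, in KMS28BM.

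Markers of other cell types were low, apart from a few genes. Medians of the T cell, NK cell, erythroid and stromal markers were at most 0.23 FPKM in any library, as were those of monocyte and epithelial markers. CD3E was at 7.32 and 20.9 FPKM in KMS18 and 1.0 and 3.27 FPKM in KMS28BM, and it rose over both lines (log2 difference 1.5, edgeR adjusted p = 0.00611). CTSS, a lysosomal protease also made by B lineage cells, was at 59.5 and 106 FPKM in KMS18 and 10.6 and 29.6 FPKM in KMS28BM (1.09, edgeR adjusted p = 0.0102). EPCAM was at 290 and 207 FPKM in KMS18 and 0.04 FPKM in both KMS28BM libraries. These markers were named after their values were seen.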

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

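The test of KMS18 cells or reads in the KMS28BM knockdown library was chosen after the class II values were seen. The genes and lists given first moved one way in KMS18 and the other way in KMS28BM on log2(FPKM + 1), with 1 library pair each, and the difference between the lines was not tested.

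Among genes, with counting intervals clear of 0 on both sides, ABLIM1 had log2(FPKM + 1) folds of 1.02 in KMS18 and -0.54 in KMS28BM, a difference of -1.55. CCL3 had -0.63 and 1.12, a difference of 1.75. FRMD6 had -0.57 and 0.90, a difference of 1.47. DNAJC25-GNG10, a readthrough of neighbouring genes, had -0.59 and 0.74, a difference of 1.33.

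Among gene lists whose percentile was extreme in a line, the ATF4 targets had medians of -0.39 in KMS18 and 0.06 in KMS28BM, a difference of 0.45. S phase genes had -0.42 and 0.03 (difference 0.45), amino acid transporters -0.37 and 0.01 (0.38), MAPK feedback genes -0.26 and 0.10 (0.36), and aminoacyl-tRNA synthetases -0.21 and 0.06 (0.26). The KMS28BM medians of S phase genes and amino acid transporters lay near 0 and took the sign of KMS18 under median of ratios (-0.013 and -0.029), upper quartile scaling (-0.021 and -0.037), TMM counts (-0.059 and -0.031) and without immunoglobulin and mitochondrial genes (-0.001 and -0.017). On TMM counts 18 of 27 S phase genes were lower in both lines, and the KMS28BM medians of the synthetases and ATF4 targets were 0.00 and 0.004, with 12 of 25 ATF4 targets lower in both lines and 1 higher in both.

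Several MHC class II genes were higher in the KMS28BM knockdown library than in its control: CD74 went from 5.63 to 51.8 FPKM, HLA-DRA from 0.91 to 4.31 FPKM and HLA-DRB1 from 1.34 to 6.51 FPKM. They were higher in the KMS18 knockdown library as well. The KMS18 control has them at 546 (HLA-DPB1) to 7267 (CD74) FPKM, so a small share of KMS18 cells or reads was tested as a technical source. The excess of 5 class II genes was 0.12% to 0.57% of their KMS18 level, and that of HLA-DQA2 (0.0075%), HLA-DRB3 (0.0505%) and HLA-DRB4 (0.0632%) was lower, while 8 genes outside class II that are abundant in KMS18 had a median excess of 0.0096%, EPCAM 0.00% and LAPTM5 0.31%, which argues against such a share for the 5 genes, since it would give every gene a like excess. A change in the cells with the knockdown, or a clone with some class II expression, may lie behind the pattern. Neither was tested, and CD74 did not pass the edgeR test over both lines.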

How the results depend on the processing

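The alternatives named as added were chosen after the data were seen: edgeR's robust and bias-adjusted fits, identifiers not summed, no immunoglobulin or mitochondrial genes, the GC and length correction, the genes with GC and length values without it, and no genes that hold AGTCTA. Camera has no robust form, so limma robust was not run for the gene lists. The knockdown calls numbered 1312 and lay between 937 and 1374 under limma, DESeq2, the stricter filter, median of ratios and the added fits other than those named next. They numbered 1765 in an uncorrected fit on the 14009 genes with GC and length values and 1231 with the correction. They fell to 367 with no filter on low counts, 419 with identifiers not summed, 196 without genes that hold AGTCTA (570 of the genes left were called in the full fit), and 0 without the replicate block, where the line difference enters the error. In that unblocked fit leaving out any 1 library also gave 0 to 0 calls by edgeR, with 27 to 46 genes at an unadjusted p under 0.05, and the lone library of an arm is assumed to vary like the others. The bias-adjusted edgeR fit was run first and gave 1315 calls before the package default took its place. The line difference of 9351 calls became 6522 in a fit of cell line alone, without construct, and 5021 to 5174 with 1 library left out of that fit (5034 without the KMS18 knockdown). With 1 residual degree of freedom a change in the gene set moves every adjusted p. Other causes were not tested.

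The size rule followed the pseudocount and the cutoff by construction. In KMS18 it passed 172 genes, 472 at pseudocount 0.1, 280 at 0.5, 460 on TMM counts and 1132 at 1.5-fold. In KMS28BM the numbers were 228, 476, 477 on TMM counts and 1158 at 1.5-fold. The shared count of 60 became 102, 109 and 401 in the same order, and the 2 opposite genes became 4 on TPM, 0 at 5 FPKM and 9 at 1.5-fold. The PRKCA fold was -2.27, -2.01 and -2.42 in KMS18 and -2.12, -1.96 and -2.27 in KMS28BM at pseudocount 0.1, 0.5 and on TMM counts. The 16 lists called by camera became 0 with an estimated correlation and 11 to 17 under the other camera settings. Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 0 (lowest adjusted p 0.0797, the unfolded protein response). It was run on the same design with 1 residual degree of freedom, so it too had little power. The lists that lost their call under at least 1 camera setting other than the estimated correlation were the PKC family, myeloma driver, oxidative phosphorylation, ATF4, amino acid transporter, interferon and proteasome lists.

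Leaving out 1 library in the unblocked knockdown fit turned the direction of some named genes, none of them called there, because a line then weighs more in 1 arm. Without the KMS18 knockdown these were GEM (-0.43), ITGB7 (-1.56), TRAF1 (-0.09) and IFIT3 (-2.00). Without the KMS28BM knockdown they were VAMP3 (-0.04), IGHA1 (-0.18), PC (-0.51), TP53INP1 (0.23) and MSMO1 (0.01). Without the KMS18 control they were TP53INP1 (0.52), ANKRD37 (0.79), MSMO1 (0.07) and HPRT1 (0.33). Without the KMS28BM control they were ITGB7 (-0.11), SLC7A11 (0.40) and PDIA4 (0.18). Under the other alternatives 0 of the called named genes changed direction.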

Other observations

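The tests chosen here after results were seen were the Gene Ontology terms and the calls and list tests without genes that hold the sequence AGTCTA, the myeloma driver list's median included. The other 3' UTR tests were written before their own result, those of the site CAGTCTA after the search that found it. Terms of the deposited annotation were tested for enrichment among the called genes, with 5328 tests and Benjamini-Hochberg adjustment. Among lower genes 10 terms passed: the IRE1-mediated unfolded protein response held 21 called genes of 65 (3.81 by chance, adjusted p = 2.84e-07, Fisher's exact test), the ER chaperone complex 9 of 12 (0.70 by chance) and the ER lumen 28 of 154 (8.95 by chance). Among higher genes 5 terms passed, with glycosphingolipid metabolic process at 8 of 30 (1.13 by chance, adjusted p = 0.00964) and endosome membrane at 18 of 171 (6.59 by chance, adjusted p = 0.0429).

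The deposited length column, which can differ between libraries for the same gene, moved alike in both lines for IFNAR2, an interferon receptor subunit. It was at 2118 and 2918 bases in KMS18 and 2172 and 2945 bases in KMS28BM. Past 0.2 on the log2 scale, 24 of 6963 genes were longer in both knockdowns, 10 shorter in both and 5 opposite.

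A short sequence in the 3' UTR went with the fall of many genes. Among 15818 sequences of 7 bases, AGTCTAA (929 carriers) had the lowest joint t of -13.80, with CAGTCTA next at -13.14, against a highest t of 4.63. In both lines 14 sequences lowered folds past -4 while 0 raised them past 4. All of the 14 but CCACACT share at least 6 bases in a row with CAGTCTAA, so they are not separate sites. CCACACT (1521 carriers) had t of -5.20 in KMS18 and -6.25 in KMS28BM (joint -6.78). Its carriers were not left out as such in the tests without AGTCTA. Of 262 genes with the full site CAGTCTAA, 30.5% fell and their median log2 fold was -0.32, against 16.2% for each site of 7 bases, 8.3% for 6 bases and 3.7% of 10097 genes without a site (median 0.03), and 10 of the 12 genes lowest in both lines, PRKCA included, carried a site of 7 or 8 bases while GAPDH and BHLHA15 did not. This is the pattern that a small RNA with this seed, such as the knockdown hairpin acting on other transcripts, may give, and 277 of 754 searched lower genes (36.7%) hold a site of 7 or 8 bases against 5.8% of higher and 10.2% of other genes. Whether the site belongs to the PRKCA hairpin cannot be told apart from chance, because the hairpin sequence was not used here and 35.3% of 1802 genes with transcripts of similar length also hold CAGTCTA, as 1 of 5 PRKCA transcripts does. GC content and transcript length also stay open in part. An uncorrected fit on the 14009 genes with such values made 1765 calls, with a median GC of 44.9% for lower, 54.8% for higher and 49% for other genes. After the correction 65.7% of these calls remained, between the 50% and 80% set in advance. All 1765 kept their sign, and their median absolute log2 fold went from 0.62 to 0.60. Of the 1312 calls of the main fit, made on 14870 genes, 1055 were also called in the same direction with the correction.

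The site's carriers do not account for the fall of 3 of the lower lists. Without genes that hold AGTCTA in any transcript, the plasma cell identity, unfolded protein response and MYC target lists kept medians at or below -0.27 in both lines, where a cause through the site needed a median above -0.1. Of the 16 called lists 12 kept their call without those genes, though a kept call did not require a like move in both lines. Without those genes the ATF4 list had medians of -0.314 in KMS18 and 0.392 in KMS28BM. The KMS28BM medians of the S phase, G2/M, proteasome and amino acid transporter lists were -0.028, -0.045, -0.064 and -0.082, above the bound of -0.1. Over all members they were -0.058, -0.071, -0.088 and -0.03, and that of the ATF4 list was 0.004. The hypoxia list also kept its call, with 8 of 17 members left, though its KMS28BM median went from -0.584 to -0.256. The myeloma driver list did not keep its call (camera adjusted p = 0.178, 8 of 22 members left, medians -0.059 and 0.084). With so few members, in a test chosen after the result was seen, an effect through the site stays open for the myeloma driver list. The interferon list (26 to 15 members) and the oxidative phosphorylation list (39 to 21) lost their calls with medians close to those before, 0.306 and 0.391 against 0.332 and 0.443, and 0.185 and 0.137 against 0.185 and 0.124, so those losses are no sign of a site effect. The PKC family kept 2 members, too few to test. Of the 8475 genes in that subset, 570 were called in the full fit, 39.1% of them lower against 59.5% of all calls, and a refit of the subset alone called 196, 36.2% lower. For the glycolysis list, the scaling of the libraries could not be judged: its highest median over the scalings was -0.049, above the bound of -0.1 set in advance, but the deposited FPKM already gave -0.052 in KMS28BM, so the bound was passed with no rescaling. A lower secretory programme after loss of PKCα may be a biological reading of these lists. It cannot be separated here from an effect of other transcripts hit through the seed. The labels give both lines the same knockdown name and no other construct against PRKCA, and more libraries of the same construct would share its seed.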
